A study of Homo sapiens with 6 samples.

How the data were processed

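RNA-seq libraries of QBC-939, a human cholangiocarcinoma (bile duct cancer) cell line, were compared between cells carrying an shRNA against WDR5 and cells carrying a scrambled control shRNA, with 3 libraries per group. The labels' protocols describe Trizol extraction of total RNA, enrichment of polyadenylated RNA, and paired-end Illumina libraries. The same protocol text also names the fraction without poly(A) tails and an adipose source, so which fraction was sequenced is uncertain. The authors deposited whole-number read counts per gene for the 6 libraries in a table of the whole series, with no normalization. The submitters' processing notes name HISAT2 2.0, StringTie 1.3.0, Bowtie 0.12.2 and DESeq2 and the builds hg19 and mm8, with no role for any of them. The counting rule, the annotation and the use of strand are not given in the sources used here. Without strand, reads from overlapping or antisense genes cannot be told apart, and reads shared by paralogs or pseudogenes may have been split, so such genes are uncertain.

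Groups came from the sample labels. The table held 32657 genes, of which 1570 had 0 counts in all 6 libraries, and all 6 of its sample columns were used. The total was 64290740 to 82214002 counts per library. At this depth, 3 counts in a library correspond to about 0.0424 CPM (counts per 1e6 counts of the library) in the knockdown libraries and 0.0378 CPM in the scramble libraries. That was the floor used for a gene at 0, and it covers counting error alone.

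Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust dispersion, R 4.3.3) on the counts as deposited. The model held the group alone, and libraries were scaled by TMM factors. The filter filterByExpr (minimum count 10, minimum total 15) kept 19771 genes, which held 99.96% of all counts, and dropped 12886. P-values were adjusted by Benjamini-Hochberg over these genes, and a gene was called at an adjusted p under 0.05. CPM values are TMM-normalised means with their SD over 3 libraries, and fold changes are WDR5 knockdown against scramble. Single genes of the series title were also given an exact two-sided permutation test of log2 CPM, whose smallest possible p with 3 against 3 libraries is 0.1. Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) when at least 3 members were tested, which held for 35 of 36 lists, with adjustment over those lists. Each was repeated with an estimated correlation and with fry. With an estimated correlation, camera uses the residual degrees of freedom of the 6 libraries, which are few. Hardly any list can then be called, so a lost call in that setting cannot decide whether a list changed. The 36 lists hold 619 distinct genes, 564 of them tested. They cover complexes, pathways and cell type markers, and 6 entries were matched through an older or newer symbol.

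The samples, the tests, the lists, the settings compared and the rule for named genes were fixed before the data were examined. The rule names WDR5, the genes of the series title (MYC, HIF1A, HDAC2 and EGLN1), and the 8 higher and 8 lower genes with the largest fold change. Those 16 had to be called, carry a gene symbol, reach at least 5 CPM in the higher group and show no overlap between groups. It also names up to 4 members of each list with the smallest p, and up to 3 members of each marker list with the highest CPM. Some genes that the rule selects are not reported here. Genes named outside it are said to be chosen after their values were seen.

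Gene positions, transcript GC content and exon overlaps were taken from GENCODE 29 on GRCh38, in which 99.6% of the gene identifiers were found. These positions do not describe the build the authors aligned to. GC content was that of the longest annotated transcript and was known for 99.7% of the tested genes. After a GC trend had been seen, each library's trend was fitted as a natural spline of GC content with 5 degrees of freedom and entered into edgeR as an offset. Other settings fixed beforehand were a replicate block, DESeq2 size factors, upper-quartile factors, library size only, no filter, a filter of 5 CPM in 3 samples, DESeq2 1.42.0, limma-voom, each library left out in turn, and rows summed per symbol. The GC correction and a count restricted to genes without exon overlap were chosen after seeing the data.

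The test was checked on simulated counts for this comparison with known changes. edgeR recovered 1.5% of 67 genes changed 1.5-fold, 38.8% of 67 changed 2-fold and 87.9% of 66 changed 4-fold. It called 6 unchanged genes among 91, with 19130 genes tested. The real comparison called 9016 genes, and with fewer changed genes the Benjamini-Hochberg adjustment is stricter. These shares therefore do not give the sensitivity of the real comparison. A simulated GC trend, linear in the same transcript GC values that the correction uses, made edgeR call 2223 unchanged genes among 2351. After the GC correction it called 13 unchanged genes among 98, with 19136 genes tested. In the same simulation, camera called a list of raised genes (adjusted p = 7.78e-72) and 0 of 36 lists of unchanged genes. Simulated genes vary independently of each other, which real genes do not, and mixed splits of the real samples gave 2 to 9 called lists.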

Results

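RNA of QBC-939 cells, a line derived from a human cholangiocarcinoma, was sequenced in 6 libraries. There were 3 libraries of cells with a scrambled shRNA and 3 of cells with an shRNA against WDR5, a scaffold of the COMPASS histone H3 lysine methyltransferases. The scramble libraries held 75423355, 82214002 and 80495599 counts and the knockdown libraries 64290740, 76113372 and 72946732. Libraries of the same group differed by more than sampling noise (chi-square per degree of freedom of 59.7 to 217.2), so all 6 were counted separately. Nothing in the labels says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The first principal component held 55.3% of the variance and separated the groups. The second held 14.7% and spread the scramble libraries alone, with scores of 71.1, 0.6 and −67.8.

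The comparison asks how the transcriptome differs in cells with an shRNA against WDR5, and the series title links WDR5 to HIF-1α through MYC, HDAC2 and the prolyl hydroxylase PHD2 (gene EGLN1), and to metastasis and epithelial-mesenchymal transition. WDR5 mRNA (ENSG00000196363; chromosome 9, 134135365 to 134159968, plus strand) was 1.35-fold lower in the knockdown libraries. HIF1A, the oxygen-regulated subunit of HIF-1, fell 2.63-fold, and EGLN1, which marks HIF-1α for degradation, rose 3.08-fold. HDAC2 was not called, except with the GC trend of each library taken off, and MYC varied more within each group than between the groups.

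WDR5 had 9557, 10433 and 11436 counts in the scramble libraries and 7339, 8433 and 8179 in the knockdown libraries. This is 141 ± 15 CPM against 105 ± 0.72 CPM (SD, n = 3), with no overlap between groups. Its log2 fold change was −0.43 (SE 0.107, edgeR adjusted p = 0.0123), and its exact permutation p of 0.1 is the smallest that 3 against 3 libraries allow. The call was lost without knockdown library 1 (adjusted p = 0.0507) or 3 (0.0536), and when scaling by library size only (−0.23, adjusted p = 0.0726), within a range of 0.00464 to 0.384 over all alternatives. With each library's GC trend taken off, WDR5 was at −0.12 (SE 0.095, adjusted p = 0.384). Exons of WDR5 overlap those of another annotated gene.

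HIF1A (ENSG00000100644; chromosome 14, 61695513 to 61748259, plus strand) went from 58.4 ± 12 to 22.2 ± 1.1 CPM, a log2 fold change of −1.39 (SE 0.162, adjusted p = 0.000404). EGLN1 (ENSG00000135766; chromosome 1, 231363751 to 231425044, minus strand) went from 23.2 ± 2.5 to 71.4 ± 3.2 CPM, a log2 fold change of 1.62 (SE 0.12, adjusted p = 0.000101). All 3 knockdown libraries lay on the same side of all 3 scramble libraries for each, the exact permutation p was 0.1 for each, and both calls were made again with the GC trend taken off (−1.76 and 1.11). HDAC2 (ENSG00000196591; chromosome 6, 113933028 to 114011308, minus strand) was at 108 ± 16 and 106 ± 9.8 CPM, a log2 fold change of −0.02 (SE 0.137, adjusted p = 0.912). Its sign changed with the scaling (0.18 by library size only), and with the GC trend taken off it was at −0.47 (adjusted p = 0.0484, the lowest of its alternatives, whose highest was 0.986). MYC (ENSG00000136997; chromosome 8, 127735434 to 127741434, plus strand) had 391, 9422 and 404 counts in the scramble libraries and 423, 10711 and 12621 in the knockdown libraries. Its log2 fold change of 1.15 (SE 1.7, adjusted p = 0.623, exact permutation p = 0.2) moved from 0.61 to 4.19 when single libraries were left out and was called in none of those fits. Exons of HIF1A and HDAC2 overlap those of another annotated gene.

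**Figure D1:**
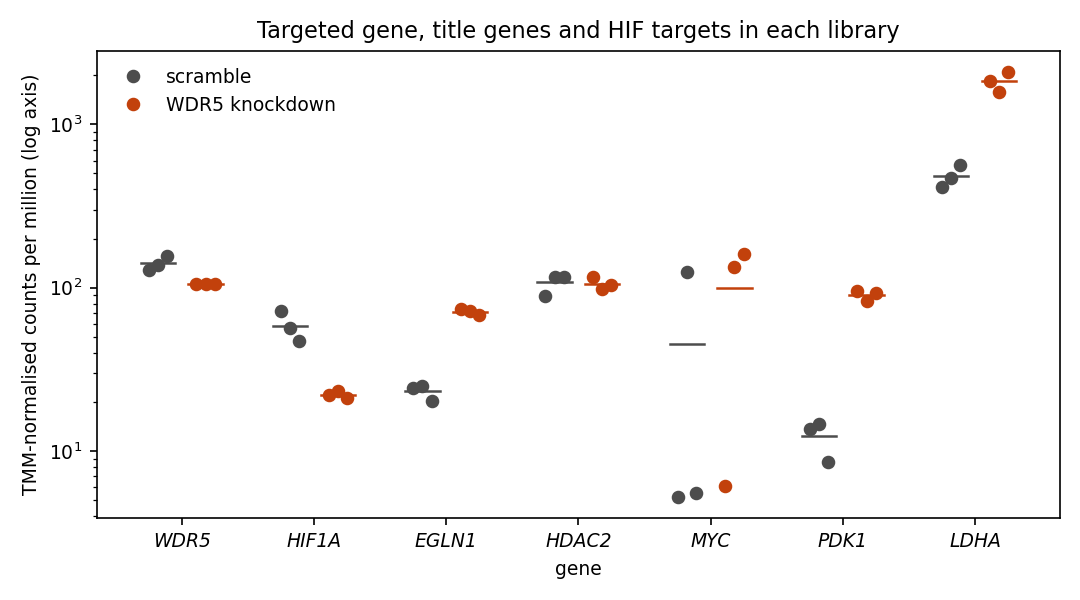
TMM-normalised CPM (log axis) of WDR5, HIF1A, EGLN1, HDAC2, MYC, PDK1 and LDHA in each scramble (grey) and WDR5 knockdown (orange) library. Points are libraries and lines are group means: WDR5 went from 141 to 105 CPM and EGLN1 from 23.2 to 71.4 CPM, while MYC is near 5 CPM in some libraries of both groups and above 100 CPM in others.

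Of 19771 genes tested, 9016 changed at an adjusted p under 0.05, with 4521 higher and 4495 lower (50.1% higher). At least 2-fold changes were seen for 4015 genes, 2377 higher and 1638 lower, against 3333 higher and 996 lower by library size only and 1201 higher and 1271 lower with each library's GC trend taken off. Scaling by library size only called 8871 genes, 63.9% of them higher, and moved the median log2 fold change of all genes from 0.034 to 0.228. Changes are given relative to the TMM scaling. The fold change followed transcript GC content, with a Spearman correlation of −0.51 across 14130 protein-coding genes, which are not independent replicates. The median log2 fold change was 0.56 for genes of 41.4 to 43.7% GC and −0.80 for genes of 62.2 to 75.8% GC. GC content weighted by the counts of non-mitochondrial genes was 52.5 ± 0.166% in scramble and 50.2 ± 0.135% in knockdown libraries (SD, n = 3). With the GC trend taken off, 6316 genes were called (3077 higher and 3239 lower), of which 4874 had the same direction in both fits, and 2472 changed at least 2-fold. Where this correction changes the counts of a gene group, its values are given beside them. For single genes, corrected values are given mainly where the call changed or the fold change moved most. A gene without such a value may have moved too. Over all alternatives, the log2 fold change of DKK1 ran from 0.43 to 1.14 and that of BAX from −1.14 to −0.52.

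**Figure D2:**
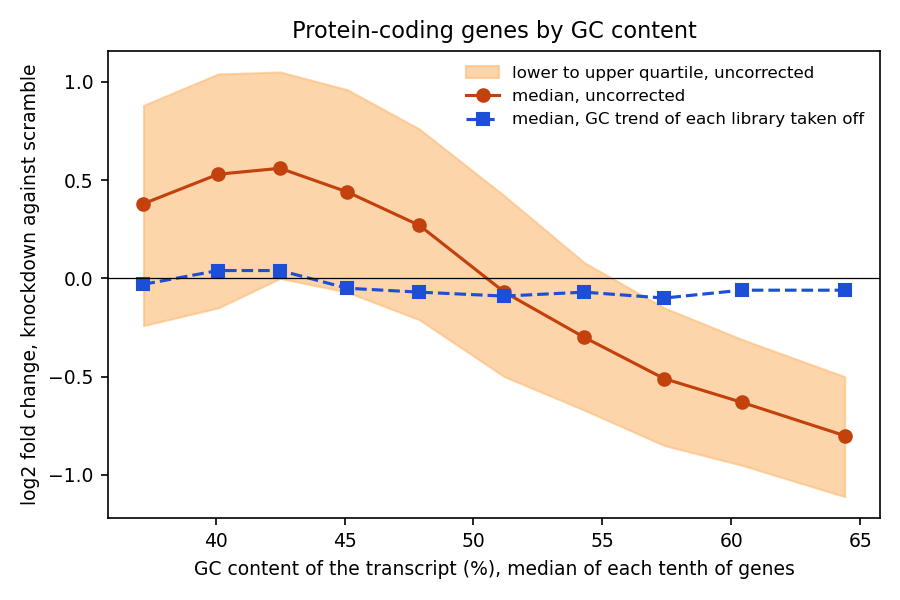
Log2 fold change of protein-coding genes (WDR5 knockdown against scramble) by transcript GC content in percent. Orange points are medians of 10 groups of genes ordered by GC content, with a band between quartiles, and blue squares are medians with each library's GC trend taken off; the uncorrected median runs from 0.38 in the lowest group to −0.80 in the highest.

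The named genes with the largest rises are both non-coding and protein-coding. The signal recognition particle RNAs RN7SL2 and RN7SL1 rose by 4.27 (SE 0.322, adjusted p = 0.000117) and 3.96 (adjusted p = 9.47e-05) on the log2 scale, from 1.28 ± 0.17 and 1.78 ± 0.44 CPM. RN7SK rose by 3.82 and RMRP, the RNA of RNase MRP, by 3.70. These RNAs, like small nucleolar RNAs, mostly lack poly(A) tails. Which fraction was sequenced is uncertain, so their counts may not reflect their levels in the cells. RN7SL1 and RN7SL2 are near-identical copies that share reads, and exons of RN7SL1, RN7SK and RMRP overlap other genes. With the GC trend taken off, RN7SL2, RN7SL1 and RMRP were at 4.94, 4.65 and 4.40. Of 35 genes of the annotation class that holds RN7SL1 and RN7SL2, 13 were higher, 2 lower and 20 not called (14 higher and 1 lower with the GC trend taken off). Of 71 small nucleolar RNA genes tested, 20 were higher, 0 lower and 51 not called (16 higher and 0 lower with the GC trend taken off). Protein-coding genes with large rises were AADAC, an arylacetamide deacetylase (3.48, from 3.75 ± 1.1 to 41.7 ± 7.8 CPM), UGT2A3, a glucuronosyltransferase (3.44), and A4GNT, a gastric-type mucin glycosyltransferase (3.24). CLDN4, a tight junction claudin, rose by 3.80 (adjusted p = 0.0107), with 621, 874 and 701 counts against 2287, 10915 and 19144. Its adjusted p was 4.59e-06 to 0.0514 over all alternatives, the highest without scramble library 1, and its log2 fold change was 3.10 without knockdown library 3.

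Large falls were seen for fetal haemoglobin genes, among others. HBG1 had 439, 473 and 499 counts in the scramble libraries and 0 in each knockdown library, at least 140-fold lower against a floor of 3 counts per library, and its paralog HBG2 had 1168, 1307 and 1324 counts against 4, 0 and 8. These paralogs share reads. SPRR1B, a cornified envelope protein, fell by 3.53 on the log2 scale (adjusted p = 0.000564). PLAU, the urokinase plasminogen activator, fell by 3.02 (adjusted p = 0.000147), from 11 ± 3.9 to 1.36 ± 0.031 CPM. The row C15orf38-AP3S2, a readthrough of adjacent genes whose reads overlap theirs, had 5713, 5118 and 5049 counts against 121, 119 and 144. The stress-induced cytokine GDF15 had 143110, 35878 and 22366 counts in the scramble libraries and 5237, 5838 and 5860 in the knockdown libraries. Its log2 fold change of −3.60 was −2.42 without scramble library 1 and −2.93 with the GC trend taken off. Its adjusted p of 0.014 (5.03e-05 to 0.0595 over all alternatives) was 0.0545 and 0.0595 without knockdown libraries 1 and 3. INHBE, an inhibin subunit, fell by 3.72 (adjusted p = 0.0428, and 0.0021 to 0.16 over all alternatives). That call was lost without scramble library 1 (−2.30, adjusted p = 0.0619), without knockdown libraries 1, 2 and 3 (0.0936, 0.0984 and 0.128), with no low-count filter (0.109), with limma-voom (0.16) and with the GC trend taken off (0.0602). BEST1, an ion channel gene, had 388, 17557 and 22258 counts against 40, 50 and 25 (log2 fold change −8.48; −9.08 and −7.88 without scramble libraries 1 and 3, −7.56 with a replicate block and −7.20 with limma-voom), and its adjusted p of 0.0141 (4.06e-10 to 0.248 over all alternatives) was 0.0587 and 0.0772 without knockdown libraries 1 and 3, 0.111 with a replicate block and 0.248 with limma-voom. Exons of HBG1, HBG2 and BEST1 overlap those of other annotated genes.

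Hypoxia-induced genes were called higher as a group, while HIF1A mRNA fell. Of 23 tested, 10 rose, 2 fell and 11 were not called (12 higher and 2 lower adjusted over the list alone; 8 and 2 with the GC trend taken off; 15 and 1 by library size only). PDK1, a kinase that inhibits pyruvate dehydrogenase, rose from 12.3 ± 3.3 to 90.7 ± 6.3 CPM, by 2.88 on the log2 scale (SE 0.209, adjusted p = 0.000101). ERO1A, an ER oxidase, rose by 2.01 (adjusted p = 0.000147), the carbonic anhydrase CA9 by 0.99 (adjusted p = 0.000519) and EGLN3 by 1.32 (adjusted p = 0.00211). Both members that fell, ADM (−0.65, adjusted p = 0.0485) and DDIT4 (−2.59, adjusted p = 0.0172), named after their values were seen, were called in no fit without a knockdown library, and 1 fell without scramble library 1 or 2. DDIT4 had 123446, 55112 and 22926 counts in the scramble libraries. Camera called the list up (adjusted p = 0.0257), with an adjusted p = 0.676 with an estimated correlation. The list's adjusted p ran from 0.00228 to 0.0737 over the fits with 1 library left out, the highest without scramble library 3, where the call was lost. None (0) of the 8 lists called by camera held with an estimated correlation, a setting whose few degrees of freedom leave little room for a call. With the filter of 5 CPM in 3 samples, where fewer genes were tested, camera called 1 list, so most of the 8 calls were lost there too.

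Glycolysis enzymes split. Of 18 tested, 4 rose, 5 fell and 9 were not called (5 and 6 adjusted over the list alone; 6 and 1 with the GC trend taken off). PGK1 rose from 743 ± 41 to 2770 ± 66 CPM (1.90, adjusted p = 9.41e-05) and LDHA, which makes lactate, from 481 ± 74 to 1840 ± 260 CPM (1.93, adjusted p = 0.000132). ALDOC rose by 0.63 (adjusted p = 0.00196), and GPI fell by 0.55 on the log2 scale (adjusted p = 0.0114). The median member was at −0.13, or 0.07 by library size only, the mean at 0.11, and the test's direction was up (adjusted p = 0.602), or down without scramble library 1 (adjusted p = 0.784). The number lower was 1 by library size only, 1 without knockdown library 1 or 3, 2 without scramble library 2 or knockdown library 2, and 3 without scramble library 3. Among 12 regulators of HIF and MYC, 3 rose, 3 fell and 6 were not called, the same adjusted over the list alone (2 and 3 with the GC trend taken off), and camera gave an adjusted p = 0.595. Besides EGLN1, EGLN3 and HIF1A, EGLN2 fell by 1.12 (adjusted p = 0.00453). Exons of PDK1, ERO1A, CA9, PGK1, ALDOC, GPI and EGLN2 overlap those of other annotated genes, and PGK1 and LDHA have processed pseudogenes.

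Some mesenchymal and some epithelial markers fell, and camera called both lists down. Of 14 mesenchymal markers tested, 0 rose, 6 fell and 8 were not called (0 and 7 adjusted over the list alone; 1 and 5 with the GC trend taken off). FN1, fibronectin, fell from 350 ± 16 to 136 ± 19 CPM (−1.36, adjusted p = 0.000182). TGFB1 fell by 1.28 (adjusted p = 0.000116; −0.59 with the GC trend taken off), smooth muscle actin ACTA2 by 1.43 (adjusted p = 0.000662) and the fibronectin receptor subunit ITGA5 by 1.93 (adjusted p = 0.00132). Camera called these markers down (adjusted p = 0.021), with an adjusted p = 0.552 with an estimated correlation. Of 23 epithelial markers, 2 rose, 12 fell and 9 were not called, the same adjusted over the list alone. Desmoplakin DSP fell from 220 ± 52 to 68.9 ± 3.8 CPM (−1.67, adjusted p = 0.000289) and the tight junction scaffold TJP1 by 1.25 (adjusted p = 0.000348). The serine protease ST14 fell by 0.90 and plakoglobin JUP by 0.84, and with the GC trend taken off both were no longer called (−0.22 and −0.22). CLDN4 and OCLN, both of tight junctions and the latter named after its value was seen, were the members that rose, of which 1 was called without scramble library 1. Epithelial markers were called down (adjusted p = 0.0257), with an adjusted p = 0.552 with an estimated correlation. That call was lost with the GC trend taken off (3 higher, 4 lower, adjusted p = 0.146), without knockdown library 1 (adjusted p = 0.0601) and without knockdown library 2 (adjusted p = 0.0535), in a range of 0.00897 to 0.0601 over the fits with 1 library left out.

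Several TGF-beta-induced genes fell. Of 12, 1 rose, 7 fell and 4 were not called, the same adjusted over the list alone (1 and 6 with the GC trend taken off), and camera did not call the list (adjusted p = 0.0648). That adjusted p was 0.0349 to 0.0915 over the fits with 1 library left out, with calls without scramble library 2 (0.0373) or 3 (0.0349), and 5 fell without any 1 of the knockdown libraries. Camera with an estimated correlation, over all libraries, gave an adjusted p = 0.647. TGFBI fell 2.01-fold, from 90.1 ± 1.1 to 44.9 ± 7.4 CPM (adjusted p = 0.000715), and ID1 and ID3 fell by 1.06 and 1.66. The member that rose, named after its value was seen, was ID2 (1.03, adjusted p = 0.023), and 0 rose without knockdown library 2. Of 23 matrix and integrin genes, 3 rose, 9 fell and 11 were not called (3 and 10 adjusted over the list alone; 4 and 9 with the GC trend taken off; 5 and 7 by library size only; camera adjusted p = 0.102). Tenascin TNC fell by 1.75 (adjusted p = 0.000156), the laminin chain LAMB1 by 0.95 (adjusted p = 0.000562) and COL6A1 by 1.42 (adjusted p = 0.000473; −0.72 with the GC trend taken off). Of 15 matrix proteases and inhibitors, 5 rose, 6 fell and 4 were not called, the same adjusted over the list alone (5 and 5 with the GC trend taken off). Besides PLAU, the inhibitors TIMP2 and TIMP1 fell by 1.24 and 1.08, and cathepsin CTSL rose by 0.95. Their median was 0.23 while the test's direction was down (adjusted p = 0.712). Exons of TGFB1, ITGA5, ACTA2, ID2, TNC, LAMB1, PLAU and TIMP2 overlap those of other annotated genes.

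YAP-induced and Wnt-induced genes were called as groups in neither case. Of 11 YAP-induced genes tested, 0 rose, 5 fell and 6 were not called, the same adjusted over the list alone (1 and 4 with the GC trend taken off; 1 and 2 by library size only; camera adjusted p = 0.214). TGFB2 fell by 0.97 (adjusted p = 0.0145, and 0.0029 to 0.054 over all alternatives), which was 0.0513 and 0.054 without knockdown libraries 1 and 2, and the number lower was 0 to 5 over the fits with 1 library left out. Those counts were 3 without scramble library 1 or 2, 1 without knockdown library 1 or 3, and 0 without knockdown library 2. Of 10 Wnt-induced genes, 2 rose, 4 fell and 4 were not called, the same adjusted over the list alone (1 and 4 with the GC trend taken off; camera adjusted p = 0.276). The Wnt inhibitor NKD1 fell from 29.5 ± 7.2 to 6.7 ± 2 CPM (−2.14, adjusted p = 0.000523), while DKK1, a secreted Wnt inhibitor, rose from 173 ± 24 to 336 ± 33 CPM (0.95, adjusted p = 0.000938). Without scramble library 1, 7 fell. Exons of TGFB2, NKD1 and DKK1 overlap those of other annotated genes.

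**Figure D3:**
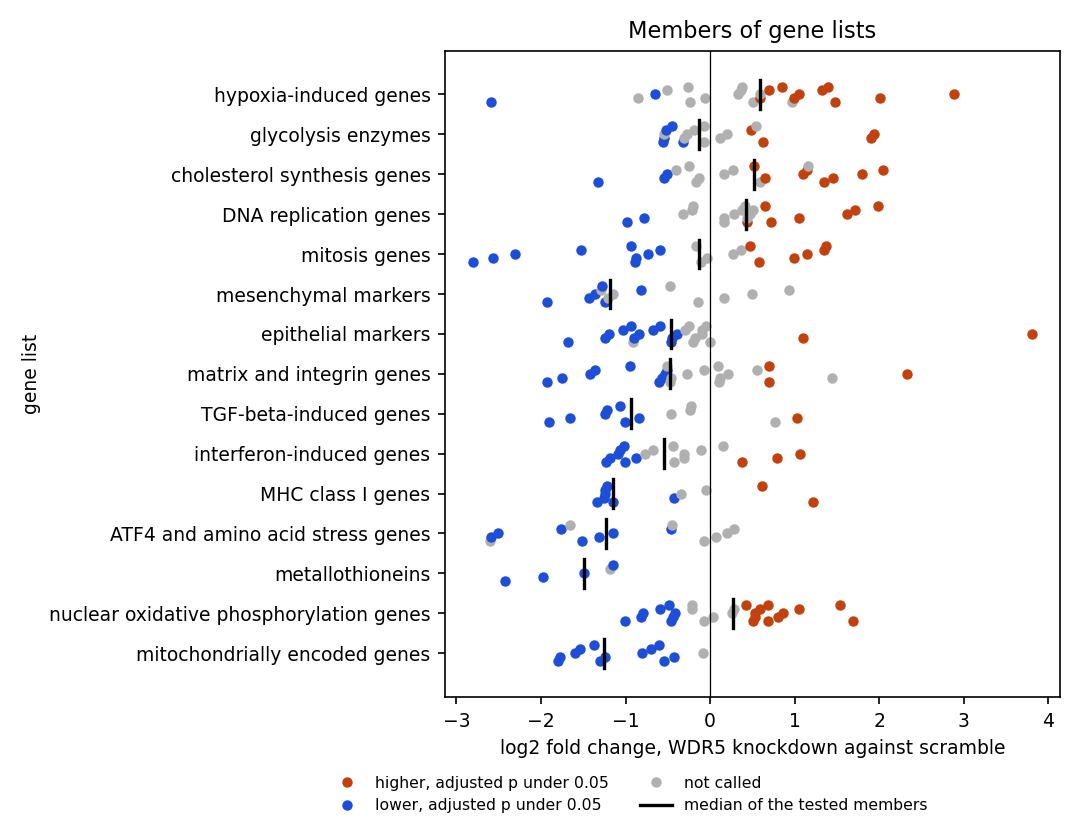
Log2 fold change (WDR5 knockdown against scramble) of each tested member of 15 gene lists, with called members in orange (higher) or blue (lower), others in grey and black bars at the medians. Mitochondrially encoded genes lie below 0 with a median of −1.25 and hypoxia-induced genes have a median of 0.59 (0.22 with the GC trend taken off), while the medians of glycolysis enzymes and mitosis genes (−0.13 each) turn positive by library size only (0.07 and 0.06).

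Subunits of the COMPASS complexes moved in both directions. Of 15, 3 rose, 9 fell and 3 were not called (3 and 10 adjusted over the list alone; 1 and 4 with the GC trend taken off; camera adjusted p = 0.118). ASH2L rose from 9.52 ± 1.1 to 19.3 ± 0.43 CPM (1.02, adjusted p = 0.000663), and the methyltransferase KMT2A fell by 0.86 (adjusted p = 0.00113). RBBP5 rose by 0.85 and KMT2B fell by 0.86, and with the GC trend taken off neither was called (0.32 and −0.16). Of 14 histone deacetylases and partners, 2 rose, 6 fell and 6 were not called, the same adjusted over the list alone (1 and 5 with the GC trend taken off; 4 and 4 by library size only; camera adjusted p = 0.355). SIN3A fell by 0.55 (adjusted p = 0.00645) and HDAC11 by 1.16 (adjusted p = 0.00135; −0.57 with the GC trend taken off). Of 29 MYC-induced genes, 10 rose, 7 fell and 12 were not called (11 and 8 adjusted over the list alone; 12 and 5 with the GC trend taken off; camera adjusted p = 0.444). ODC1, the rate-limiting enzyme of polyamine synthesis, rose from 242 ± 34 to 549 ± 34 CPM (1.18, adjusted p = 0.000323), while spermidine synthase SRM fell by 1.59 (adjusted p = 0.000263; −0.88 with the GC trend taken off). POLR1B, a subunit of RNA polymerase I, rose by 1.65 and PRMT3 by 1.22. Exons of ASH2L, KMT2A, KMT2B, SIN3A and HDAC11 overlap those of other annotated genes.

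Of 77 ribosomal protein genes, which have many processed pseudogenes, 32 rose, 21 fell and 24 were not called (33 and 22 adjusted over the list alone; 20 and 15 with the GC trend taken off). Their median was 0.09, or −0.07 with the GC trend taken off, and camera gave an adjusted p = 0.388. RPL28 fell from 1980 ± 180 to 524 ± 55 CPM (−1.92), while RPS25 rose from 238 ± 37 to 842 ± 160 CPM (1.82). Of 20 DNA replication genes, 7 rose, 2 fell and 11 were not called, the same adjusted over the list alone (6 and 1 with the GC trend taken off; 11 and 2 by library size only). GINS1, of the replicative helicase, rose from 28.2 ± 4.4 to 92.5 ± 2.9 CPM (1.71, adjusted p = 0.000115) and the helicase subunit MCM4 by 1.62. The transcription factor E2F1 fell by 0.78 (adjusted p = 0.000614; −0.12, not called, with the GC trend taken off). The list's adjusted p of 0.0829 became 0.0357 by library size only, 0.0387 with the GC trend taken off and 0.00842 without scramble library 3, in a range of 0.00842 to 0.246 over the fits with 1 library left out. Camera with an estimated correlation, over all libraries and without the GC correction, gave an adjusted p = 0.747. Exons of RPL28 and RPS25 overlap those of other annotated genes.

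Mitosis genes were called in both directions. Of 20, 6 rose, 9 fell and 5 were not called, the same adjusted over the list alone, and camera gave an adjusted p = 0.276. The cyclins CCNB1, CCNA2 and CCNB2 rose by 1.37, 1.35 and 1.15, CCNB1 from 81.5 ± 7.7 to 210 ± 13 CPM (adjusted p = 0.000132). The kinetochore protein gene CENPF fell from 29.7 ± 2.8 to 6.01 ± 0.54 CPM (−2.30, adjusted p = 9.41e-05). With the GC trend taken off, 3 rose and 10 fell, and the list was called down (adjusted p = 0.00822), against 0.0767 to 0.409 over the fits with 1 library left out. Camera with an estimated correlation, over all libraries and without the GC correction, gave an adjusted p = 0.807. Of 18 p53-induced genes, 2 rose, 7 fell and 9 were not called (3 and 7 adjusted over the list alone; 2 and 3 with the GC trend taken off; camera adjusted p = 0.276). SESN1 rose by 2.19 (adjusted p = 0.00085) and the p53 ligase MDM2 by 1.34 (adjusted p = 0.000409), while the pro-apoptotic BAX fell from 132 ± 16 to 65.1 ± 2.9 CPM (−1.02, adjusted p = 0.000391). FDXR was at −0.59 (adjusted p = 0.00704) and at 0.04 with the GC trend taken off. The number lower was 2 and 3 without knockdown libraries 1 and 3, and CDKN1A, named after its value was seen, had 18524, 2399 and 1254 counts in the scramble libraries. Of 14 replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, 1 rose, 2 fell and 11 were not called (0 and 1 adjusted over the list alone; 0 and 2 with the GC trend taken off). None (0) rose without scramble library 1 or knockdown library 1 or 2, and 1 fell without knockdown library 1 or 3. The linker histone HIST1H1C fell by 1.24 (adjusted p = 0.000402), and the list's mean was 0.14 while the test's direction was down (adjusted p = 0.712). Exons of CCNA2, MDM2 and SESN1 overlap those of other annotated genes.

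Mitochondrial transcripts were lower in the knockdown libraries. Mitochondrial genes held 17.4 ± 0.55% of counts in the scramble libraries and 11.3 ± 0.649% in the knockdown libraries (SD, n = 3). Of 13 mitochondrially encoded protein genes, 0 rose, 12 fell and 1, MT-CO1, was not called, the same adjusted over the list alone, and 13 fell with the GC trend taken off. MT-CYB fell from 12000 ± 1000 to 3440 ± 110 CPM (−1.80, adjusted p = 9.41e-05) and MT-ND4 from 21600 ± 2200 to 7130 ± 280 CPM (−1.60, adjusted p = 0.000107). Camera called them down (adjusted p = 4.47e-09), with an adjusted p = 0.647 with an estimated correlation. Nuclear copies of mitochondrial sequence share reads with these genes. Of 26 nuclear genes of oxidative phosphorylation, 12 rose, 8 fell and 6 were not called (13 and 8 adjusted over the list alone; 6 and 4 with the GC trend taken off; camera adjusted p = 0.276). NDUFS1, of complex I, rose from 55.2 ± 3.5 to 178 ± 13 CPM (1.69, adjusted p = 9.41e-05) and the ATP synthase subunit ATP5C1 by 1.54. CYC1, of complex III, fell by 0.80 (adjusted p = 0.000824; −0.06, not called, with the GC trend taken off). Without knockdown library 3, 5 of the list fell. Exons of MT-ND4 and NDUFS1 overlap those of other annotated genes.

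Camera called cholesterol synthesis genes higher as a group, though not in every fit. Of 19, 8 rose, 3 fell and 8 were not called, the same adjusted over the list alone (6 and 1 with the GC trend taken off). The isomerase IDI1 rose from 23.2 ± 3.7 to 96 ± 8.4 CPM (2.05, adjusted p = 0.000101). MSMO1 rose by 1.79, the sterol carrier STARD4 by 1.45 and CYP51A1, lanosterol demethylase, by 1.34. The list was called up (adjusted p = 0.0417), with an adjusted p = 0.676 with an estimated correlation. Over the fits with 1 library left out, the call was lost without scramble library 1 (adjusted p = 0.0828) or 2 (0.0518) and without knockdown library 2 (0.0754), in a range of 0.0223 to 0.0828. Of 12 NRF2-induced genes, 5 rose, 3 fell and 4 were not called, the same adjusted over the list alone (5 and 1 with the GC trend taken off; camera adjusted p = 0.181). Thioredoxin reductase TXNRD1 rose from 83.7 ± 13 to 412 ± 82 CPM (2.30, adjusted p = 0.00012), GCLC by 1.13 and AKR1C1, which has close paralogs, by 1.31. Exons of IDI1, CYP51A1, STARD4 and GCLC overlap those of other annotated genes.

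Some ATF4 and amino acid stress genes fell, and CHAC1 also varied between the scramble libraries. Of 14, 0 rose, 7 fell and 7 were not called (0 and 8 adjusted over the list alone; 0 and 3 with the GC trend taken off). PHGDH, of serine synthesis, fell from 259 ± 58 to 104 ± 13 CPM (−1.31, adjusted p = 0.000844). CHAC1 fell by 2.51 (adjusted p = 0.00619), or by 1.91 without scramble library 1 and by 1.86 with the GC trend taken off, and CEBPB and SLC3A2 fell by 1.52 and 1.15 and were not called with the GC trend taken off (−0.73 and −0.74). CHAC1 had 6093, 3063 and 1622 counts in the scramble libraries. ATF3, of the same list and named after its values were seen, had 7046, 1212 and 363. DDIT4, GDF15 and INHBE were likewise highest in scramble library 1 and lowest in scramble library 3, so these genes also varied within the scramble group. The list was called down (adjusted p = 0.0257), with an adjusted p = 0.702 with an estimated correlation. Over the fits with 1 library left out, its adjusted p ran from 9.78e-06 without scramble library 3 to 0.0517 without scramble library 1, where the call was lost. Without knockdown library 1 or 3, 4 fell. Of 13 ER chaperone genes, 3 rose, 5 fell and 5 were not called, the same adjusted over the list alone (2 and 4 with the GC trend taken off). Their median was −0.11, or 0.06 by library size only, and camera gave an adjusted p = 0.696. EDEM1 and DNAJC3 rose by 1.17 and 0.97, and HYOU1 fell by 0.69. Of 5 metallothioneins tested, near-identical zinc-binding paralogs that may share reads, 0 rose, 4 fell and 1 was not called, the same adjusted over the list alone (0 and 3 with the GC trend taken off). MT1F fell from 11.7 ± 1.3 to 5.28 ± 1.2 CPM (−1.15, adjusted p = 0.00196). Metallothioneins were called down (adjusted p = 0.035), with an adjusted p = 0.676 with an estimated correlation, and without scramble library 1 the adjusted p was 0.0555 (2.69e-07 to 0.0555). The number lower was 2 without scramble library 1 and 1 without scramble library 3 or knockdown library 1. Exons of CEBPB, EDEM1 and HYOU1 overlap those of other annotated genes.

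Several genes of antigen presentation fell. Of 11 MHC class I genes, 2 rose, 7 fell and 2 were not called, the same adjusted over the list alone (1 and 6 with the GC trend taken off). HLA-B fell from 129 ± 4.5 to 54.6 ± 1.7 CPM (−1.24, adjusted p = 0.000107), and it is polymorphic and shares reads with its paralogs. The peptide transporter TAP1 and the immunoproteasome subunit PSMB8 fell by 1.22 and 1.15. The members that rose, named after their values were seen, were B2M, the light chain (1.22, adjusted p = 0.000333), and the peptidase ERAP1 (0.62, adjusted p = 0.00817; 0.15, not called, with the GC trend taken off). Camera called MHC class I genes down (adjusted p = 0.021), with an adjusted p = 0.624 with an estimated correlation. Of 18 interferon-induced genes tested, 3 rose, 7 fell and 8 were not called, the same adjusted over the list alone (camera adjusted p = 0.118). ISG15 fell from 108 ± 10 to 46.2 ± 4 CPM (−1.23, adjusted p = 0.000205; −0.53 with the GC trend taken off) and IFI6 by 1.09, while OAS1 rose by 1.06. With the GC trend taken off, 1 rose, 10 fell and the list was called down (adjusted p = 0.0387), as it was without scramble library 3 (0.0495, the lowest of the fits with 1 library left out, whose highest was 0.164). Camera with an estimated correlation, over all libraries and without the GC correction, gave an adjusted p = 0.676. Of 14 NF-kB and cytokine genes tested, 0 rose, 3 fell and 11 were not called, the same adjusted over the list alone and with the GC trend taken off (camera adjusted p = 0.276). Their median was −0.10, or 0.09 by library size only. ICAM1 fell from 78.4 ± 14 to 37.4 ± 1.8 CPM (−1.07, adjusted p = 0.000672). NFKB2 fell by 1.41 (−0.75 with the GC trend taken off) and RELB by 1.91 (−1.16). Of 15 immediate early genes tested, 0 rose, 4 fell and 11 were not called (0 and 3 adjusted over the list alone; 0 and 2 with the GC trend taken off; camera adjusted p = 0.0854). NR4A1 fell by 1.06 (adjusted p = 0.000365) and FOSL1 by 1.92 (adjusted p = 0.00558), and without knockdown library 1 or 2 the number lower was 2. The list's adjusted p was 0.0168 to 0.215 over the fits with 1 library left out, with calls made without scramble library 2 (0.0168) or 3 (0.0223). Camera with an estimated correlation, over all libraries, gave an adjusted p = 0.747. Exons of HLA-B, TAP1, PSMB8, ERAP1, ISG15, OAS1, ICAM1 and NR4A1 overlap those of other annotated genes.

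The bile duct markers with the highest CPM were not called, while others on their list rose or fell. EPCAM was at 485 ± 50 and 409 ± 27 CPM, KRT19 at 462 ± 100 and 407 ± 56 CPM and CD24 at 381 ± 110 and 544 ± 31 CPM, and none of the 3 was called (adjusted p of 0.121, 0.444 and 0.0651). The sign of KRT19, −0.18, turned by library size only (0.02) and with the GC trend taken off (0.45). EPCAM was called without scramble library 1 (−0.34) and with the GC trend taken off (−0.65), in a range of adjusted p of 0.00279 to 0.734. CD24 was called by library size only (0.72), without scramble library 3 (0.78), and with a replicate block, the filter of 5 CPM or limma-voom (0.55, 0.56 and 0.55), in a range of 0.00239 to 0.908. Of 17 cholangiocyte markers tested, 5 rose, 5 fell and 7 were not called (7 and 6 adjusted over the list alone; 5 and 5 with the GC trend taken off; camera adjusted p = 0.657). The annexin ANXA4 rose from 93.3 ± 10 to 238 ± 5.2 CPM (1.35, adjusted p = 0.000129) and matrilysin MMP7 from 42.4 ± 10 to 181 ± 66 CPM (2.10, adjusted p = 0.00262), while trefoil factor TFF3 fell by 1.82 (adjusted p = 0.00181). Of 11 squamous markers tested, 2 rose, 4 fell and 5 were not called, the same adjusted over the list alone (2 and 1 with the GC trend taken off; camera adjusted p = 0.243), and 1 rose without scramble library 1 or 2 or knockdown library 1 or 3. The serpin SERPINB5 rose by 1.31 (adjusted p = 0.0002), and SFN fell from 122 ± 27 to 57.5 ± 4.5 CPM (−1.08; −0.41, not called, with the GC trend taken off). Of 6 hepatocyte markers tested, 0 rose, 1 fell and 5 were not called (1 and 3 adjusted over the list alone; 1 and 2 with the GC trend taken off; camera adjusted p = 0.388). SERPINA1 was at 1350 ± 150 and 1050 ± 120 CPM (adjusted p = 0.0548, and 0.0158 to 0.425 over all alternatives). It was called without scramble library 1 (0.0158), with DESeq2 or its size factors, with upper-quartile factors and with limma-voom (0.0403 to 0.0499). HNF4A fell by 0.69 (adjusted p = 0.0205, and 0.00424 to 0.0672), which was not called without knockdown libraries 1, 2 and 3 (0.0633, 0.0561 and 0.0672) or by library size only (0.0591).

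Among markers of other cell types, several blood-cell genes fell. Of 4 fibroblast markers tested, 0 rose, 1 fell and 3 were not called (0 and 2 adjusted over the list alone; 0 and 1 with the GC trend taken off; camera adjusted p = 0.273), and THY1, the member that fell, had 17, 32 and 18 counts against 2, 0 and 0. Of 5 endothelial markers, 0 rose, 1 fell and 4 were not called, the same adjusted over the list alone and with the GC trend taken off (camera adjusted p = 0.381), with PECAM1 at 1.35 ± 0.1 and 0.538 ± 0.093 CPM (adjusted p = 0.00513). Of 2 adipocyte markers tested, 1 rose and 1 was not called, too few for camera, and CIDEC, at 7.28 ± 1.2 and 11.1 ± 2.5 CPM (adjusted p = 0.0424), was not called without scramble library 1 or 2 (0.117 and 0.11), without knockdown library 1 or 3 (0.0888 and 0.164), or with DESeq2 or upper-quartile factors (0.0541 and 0.0508), in a range of 0.00811 to 0.164. Of 5 leukocyte markers tested, 1 rose, 3 fell and 1 was not called, the same adjusted over the list alone (0 and 2 with the GC trend taken off; camera adjusted p = 0.181). The leukocyte antigen PTPRC had 16, 37 and 21 counts in the scramble libraries and 0 in each knockdown library. LAPTM5 had 512, 509 and 497 counts against 100, 166 and 88 (−2.14, adjusted p = 0.000368). Lysozyme LYZ, which epithelia also express, rose by 0.72 from 1350 ± 230 to 2210 ± 93 CPM (adjusted p = 0.004; 0.21, not called, with the GC trend taken off), and its exons, like those of THY1, overlap other genes. Other blood-cell genes were picked out for naming after their values were seen. HBA1 had 883, 1116 and 1040 counts against 153, 272 and 114, ITGA2B 286, 276 and 306 against 0, 6 and 4, and TAL1 74, 146 and 84 against 0, 4 and 0. The haemoglobin gene HBE1 was alike in both groups, with 126, 79 and 77 counts against 81, 73 and 131, and the macrophage marker CD68 was not called (adjusted p = 0.825).

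**Figure D4:**
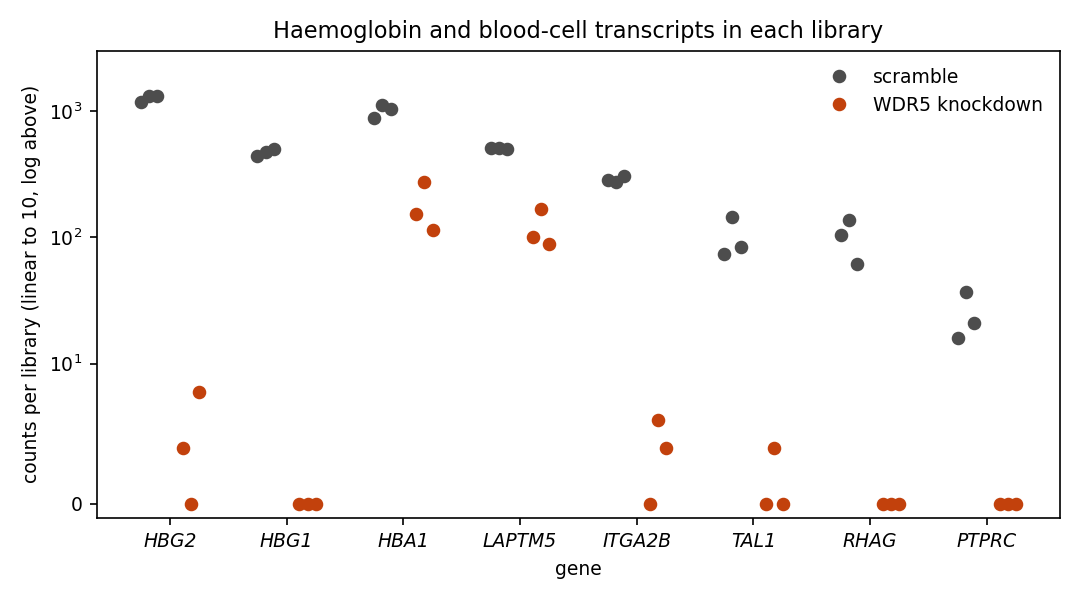
Counts per library (linear to 10, log axis above) of haemoglobin genes HBG2, HBG1 and HBA1 and of LAPTM5, ITGA2B, TAL1, RHAG and PTPRC in scramble (grey) and WDR5 knockdown (orange) libraries, with points as libraries. HBG1, RHAG and PTPRC are at 0 in all 3 knockdown libraries, where HBA1 has 114 to 272 counts.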

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

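The GC correction and the count of genes without exon overlap were tests chosen after the results were seen, and all other alternatives were planned. Of 162 named genes besides WDR5, 143 were called, of which 35 lost the call with the same sign in at least 1 setting and 1, FDXR, turned sign and lost it. Among planned settings, library size only gave WDR5 at −0.23 (adjusted p = 0.0726) and turned the sign of HDAC2 (0.18), KRT19 (0.02), TTR (0.17) and CD68 (0.13), none of them called, since every log2 value moves up with that scaling. The filter of 5 CPM in 3 samples left 2501 genes changed at least 2-fold and 1 called list, with fewer genes tested, and HDAC2 (0.02) and TTR (0.01) changed sign. No low-count filter gave 15 called lists, the DESeq2 test 14 and fry 18, for which the cause was not tested. An estimated inter-gene correlation gave 0. That setting rests on the few residual degrees of freedom of the libraries, so its 0 cannot show that the calls fail. The estimated correlation was −0.003 for mesenchymal and −0.005 for epithelial markers, below the preset 0.01. Correlated members therefore do not explain the loss of these calls. It was 0.051 to 0.821 for the other lists called with the preset correlation. Fits that left out 1 library called 7005 to 9302 genes, 3475 to 4061 of them at least 2-fold, and 5 to 11 lists, the lowest without scramble library 1. Over those fits, with fewer samples, WDR5 ran from −0.52 to −0.35, HDAC2 from −0.16 to 0.04, VWF from −2.09 to 0.03, CDH5 from −0.63 to 2.35, TTR from −0.23 to 0.16 and CD68 from −0.24 to 0.11. The GC correction left 2472 genes changed at least 2-fold, put WDR5 at −0.12, and turned FDXR (0.04), KRT19 (0.45), COL1A1 (0.14), PDGFRB (0.01) and CD68 (0.25) positive, each a gene whose transcript lies in the GC range that the correction raises. Genes without exon overlap gave 4752 called and 2210 at least 2-fold, as fewer genes entered. Libraries with the same number did not deviate together (correlations of −0.002, −0.011 and −0.023), so the numbers do not pair them. With the replicate block 8199 genes and 11 lists were called, and no library correlated best with the one of its own number. Depth limits genes of under 10 counts per library, which the filter removed.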

Other observations

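Pathways named in the deposited table itself were tested after the results had been seen. Of 304 with at least 10 tested members, camera called 18, of which 1 was up and 17 down; 10, all down, were called in the same direction with the GC trend taken off, and 0 with an estimated correlation (adjusted p of 0.277 to 0.287). Cell adhesion molecules had 11 members higher and 34 lower of 88 (adjusted p = 0.00677, and 0.277 with an estimated correlation), and focal adhesion had 25 higher and 70 lower of 165 (adjusted p = 0.0211, and 0.277). Genes named from them were chosen after their values were seen. In focal adhesion, the cytoskeletal actin ACTB fell by 1.40 and zyxin ZYX, a focal adhesion adaptor, by 1.89 (−1.14 with the GC trend taken off), while CAV1 and CAV2, of caveolae, rose by 1.79 and 2.02 and the GTPase CDC42 by 1.44. The adhesion receptor NECTIN2 fell by 1.41 and CTNNB1, beta-catenin, rose by 1.75.

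Ascorbate and aldarate metabolism was the pathway called up, with 8 members higher and 1 lower of 16 (adjusted p = 0.0227, 0.277 with an estimated correlation, and 0.125 with the GC trend taken off). UGDH, which makes UDP-glucuronic acid, rose by 1.03, and the glucuronosyltransferases UGT1A6 and UGT1A7 rose by 1.47 and 1.66. UGT1A6 and UGT1A7 share exons and reads, so they are not independent. UGT1A10, of the same family and named after its values were seen, had 24, 9333 and 8114 counts in the scramble libraries. Its exons overlap those of another gene, so how reads were split among these rows is uncertain. Endocrine and other factor-regulated calcium reabsorption had 1 member higher and 21 lower of 35 (adjusted p = 0.0115, and 0.277 with an estimated correlation). Its members include the clathrin adaptor AP2A1 (−1.01, and −0.36 with the GC trend taken off), the clathrin light chain CLTA (−0.99) and the kinase PRKACA (−1.23).

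The tests on GC content, on the neighbours of MYC and on splits by the number of changed genes were chosen after their results were seen; the tests on erythroid markers, on exon overlap and on splits by the number of lists were not. The fold change between groups followed GC content (Spearman −0.51 across genes), more than any pair of libraries of the same group did (−0.22 to 0.26). Taking the trend off called 4874 genes again in the same direction, which argues against the fitted trend as the whole cause of the changed genes. The correction used 1 GC value per gene, that of the longest transcript. It cannot exclude another GC-dependent or technical difference between the groups as a cause of the rest. For WDR5 itself it left −0.12 (SE 0.095) from −0.43 (SE 0.107), and 640 coding genes of its GC content and at least 10 CPM had a median of −0.38, so the lower WDR5 count is consistent with a GC-dependent yield of the libraries. A partial knockdown of WDR5 mRNA stays open and untested, and protein levels were not analysed here. Other splits of the 6 samples numbered 10 with the real one, too few for a share under 0.05: the real split gave 9016 changed genes against 1 at most in the others and 4015 against 1 at least 2-fold (1 of 10 as large in each), and 8 called lists against 9 (3 of 10). Each other split mixes libraries of both groups, so the group difference widens its spread and few changed genes follow from the design. The counts of changed genes thus cannot show whether the group difference is technical.

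Transcripts of several haemoglobin and blood-cell genes, such as HBG1, HBG2 and PTPRC, were present in the scramble libraries and low or absent in the knockdown libraries. Of 18 erythroid lineage genes listed before their own counts were seen, 16 were detected and 13 had more CPM in every scramble library than in every knockdown library, and 0 went the other way. Chance gives 5% in this direction (10% for any separation). Of the 25085 other detected genes, 17.8% separated this way, a share worked out after the result was seen. HBE1, NFE2 and SLC4A1 did not separate, and 5 of the 16 had at least 10 counts in every knockdown library too. AHSP had 0 counts in every library and HBZ had 4 in scramble library 2 alone. ALAS2 had 12, 19 and 16 counts against 3, 12 and 4 and was not called (edgeR adjusted p = 0.156). Outside that list, HBG2 was at 17.1 CPM and HBA1 at 13.7 CPM, with HBB at 0, 8 and 4 counts in the scramble libraries, so RNA of erythroid or erythroleukaemia-like cells in the scramble libraries is a candidate source. Expression of these genes by the scramble cells themselves, and less with the shRNA, stays open and untested.

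Some genes differed more between libraries of the same group than between the groups, MYC among them. Of 11321 genes above 5 CPM, 73 differed over 8-fold within a group, and 65.8% of these had an exon overlap against 49.7% of the others (odds ratio 1.94, 95% interval 1.17 to 3.29, Fisher's exact p = 0.00672), so reads moved between overlapping genes may account for part of them. The test took rows as independent, yet overlapping partners such as RAB43 and ISY1-RAB43 both entered, so its p and interval are too narrow. MYC is among the 25 of the 73 with no exon overlap. Among 20 other rows within 1 Mb of MYC, the largest count in any library was 3089 (CASC19), below the 9031 counts by which MYC differed between scramble libraries, which argues against its reads having gone to a neighbouring row. Another step of the counting and a true difference in MYC between cultures both stay open and untested.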
